A study of Rattus norvegicus with 42 samples.

How the data were processed

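Total RNA of liver, brain and lung from 1 rat was labelled and hybridised to Affymetrix rat GeneChip arrays, as pure tissue or after mixing the cRNA, with 3 technical replicate arrays for each of 14 groups. The authors normalized the arrays with RMA, per the labels' protocols and the submitters' processing notes, and the deposited values are log2 levels per probe set between 2.12 and 14.43. The RMA version is not given in the sources used here. RMA gives arrays similar distributions of values, so tissues that differ in how their RNA is spread over genes may be scaled unevenly. The table holds 31099 probe sets, of which 57 control probe sets were left out of the tests, leaving 31042. No replicate pair of arrays was identical, and at most 28 probe sets had equal values in a pair, so each array counted as 1 replicate.

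Gene names came from the platform annotation. 20826 probe sets had 1 gene, 436 had several and were not named, and 9780 were not listed there. A look-up of gene identifiers in the GRCr8 gene table changed 0 symbols, and 68 without a match kept the annotation's name. For gene-level statements 1 probe set per gene was used, that with the highest mean over all arrays, which gave 14217 genes.

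All 42 arrays entered 1 limma fit (limma 3.58.1, R 4.3.3) with a mean per group, 28 residual and 4.56 prior degrees of freedom. P-values were adjusted by Benjamini-Hochberg over all tested probe sets. Pure tissues were called different at adjusted p under 0.05 and at least 2-fold. A probe set was enriched in a tissue when called higher than in both others, and enriched probe sets were ranked by the smaller of both differences. A departure from linear mixing was the mean over mixtures of the observed log2 level minus that of the share-weighted sum of pure means, with its error from the fit by the delta method, called at 1.5-fold. Shares were estimated by non-negative least squares on linear values of the 100 top probe sets per tissue, each divided by its highest pure mean, and rescaled to a sum of 100%. Lowest shares were tested against the sum without the tissue. Pairs of mixtures were called at adjusted p under 0.05 with no fold limit. The mixtures-only regression used the 11 mixture means on the linear scale with limma's variance trend, and was called at adjusted p under 0.05 with no fold limit. The 27 gene lists were tested with camera at a preset correlation of 0.01 and with an estimated one, over 49 tests.

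Designs, lists, alternatives and the rule for named genes were fixed before the data were examined, except where the text says otherwise. Named were the 10 genes with the largest smaller difference per tissue, the 3 leading members of each list with a home tissue and any member at least 2-fold higher elsewhere, up to 4 members of the other lists, the 5 largest departures each way, and the 3 largest calls each way per pair. Alternatives covered the arrays in the fit, the variance model, median centring, a repeated quantile normalization, a filter on dim probe sets (highest group mean over the median, 5.73), 1 probe set per gene, background subtraction (the 5th percentile), the scale of mixing, the probe sets and limits of the share estimate, and leaving out each array. Added after seeing the data were share estimates by brightness and a shift of each array by a curve through its 4 hybridisation controls (bioB, bioC, bioD and cre). That shift takes them as added in equal amounts to each array, which was not tested. Values below the dimmest control, bioB, took the bioB shift, and values above cre that of cre.

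The steps were tested on simulated arrays drawn from the pure means and the fitted spread of 31042 probe sets. For a pair of mixtures with 200 changed probe sets, 46.0% were recovered at 1.25-fold, 90.0% at 1.5-fold and 100.0% at 2-fold and 4-fold, with 15 false calls. For departures, 0.0% were called at 1.25-fold, 100.0% at 2-fold, with 0 false calls. Shares of exact linear mixtures were recovered with mean absolute errors of 0.17, 0.15 and 0.06 points for liver, brain and lung. From mixtures alone, 99.2%, 97.9% and 97.9% of the pure calls of liver against brain, liver against lung and brain against lung were recovered. Of 100 top lung probe sets 78 were called at a simulated 1% of lung and 0 at 0%. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.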

Results

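Gene expression was measured on Affymetrix rat GeneChip arrays in liver, brain and lung of 1 animal, alone and after their labelled RNA (cRNA) had been combined in known amounts. The 42 arrays formed 14 groups of 3 technical replicates: 3 pure tissues and 11 mixtures. Mixtures are named here by their labelled percentages of liver, brain and lung in that order, as in 65/34/1. The labels give the purpose as a test of whether, and with what sensitivity, tissue composition can be recovered statistically. Array medians lay between 5.48 (log2, a liver array) and 5.83 (a 5/25/70 array). The median SD between replicate arrays was 0.12 (log2) in liver, 0.09 in brain and 0.09 in lung. The number of arrays limits the precision, and because all replicates are arrays of the same RNA, p-values measure only the spread between arrays and carry nothing about differences between animals.

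Liver stood apart from both other tissues by enzymes and secreted proteins of hepatocytes. The sulfotransferase gene Sult1b1 had a level of 11.74 ± 0.01 (log2, SD, n = 3) in liver and 3.11 ± 0.16 in brain, the next tissue, a 398-fold difference. Levels near 3 are close to those of the bacterial dap control probe sets, which read 2.43 to 3.09 in the pure tissues, so folds against such levels, here and for brain and lung genes, are approximate and so is the ranking by them. Serpina6, which encodes corticosteroid-binding globulin, was 343-fold higher than in the next tissue, Amy1 333-fold, Hsd17b6 328-fold, the lectin gene Mbl2 323-fold and the glucose transporter gene Slc2a2 292-fold. Mug1, Ugt2b35, Cyp2c22 and Bhmt2 completed the 10 genes with the largest differences, at 317-fold, 309-fold, 291-fold and 262-fold. By list, 20 of 21 measured genes of plasma proteins were enriched in liver, meaning at least 2-fold higher than in both other tissues, with F2 (prothrombin) 260-fold and F9 241-fold higher. Some liver transcripts, named after their values were seen, were higher in brain than in lung by limma: Alb (albumin) was at 14.31 in liver, 12.21 in brain and 5.07 in lung (brain against lung adjusted p = 7.33e-41), Apoc3 at 7.71 in brain and 4.70 in lung (6.48e-34), Apoh at 6.75 and 3.78 (1.87e-33), and Hpd at 5.61 and 3.19 (1.86e-25). Ttr, the plasma protein gene that was not enriched, was at 13.33 in liver and 13.09 in brain. Other liver genes went the other way, such as Pck1 at 4.98 in brain and 6.23 in lung and Fbp1 at 4.41 and 5.35. List medians in brain and lung were 6.01 and 3.97 for plasma proteins and 5.23 and 4.29 for urea cycle and amino acids. They were 4.11 and 4.10 for drug and steroid metabolism, 3.92 and 3.79 for bile acids, and 4.41 and 5.35 for glucose production. All 12 measured genes of bile acid synthesis and transport were enriched, among them the uptake transporters Slco1b2 (254-fold) and Slc10a1 (240-fold). All 12 of the urea cycle and amino acid breakdown were enriched, with Tdo2 258-fold, Hpd 183-fold and Otc 137-fold higher, and so were all 5 of glucose production and glycogen, including Fbp1 (138-fold) and Pck1 (69.7-fold). Drug and steroid metabolism had 11 of 16 enriched genes, led by Ces1c (231-fold), Cyp1a2 (194-fold) and Cyp4a1 (162-fold). Each of these counts was equal when adjusted over the list alone. In all, 2259 probe sets (7.28% of 31042) were enriched in liver. That count was 3463 after centring arrays on their medians and 1145 after a curve through the hybridisation controls.

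Brain was marked by myelin and synapse genes. The myelin genes Mobp and Mbp were 753-fold and 523-fold higher than in the next tissue, with Mbp at 13.71 ± 0.06 (log2, SD, n = 3) in brain and 4.68 ± 0.21 in liver. Snap25, part of the machinery of transmitter release, was 511-fold higher, Ptgds 402-fold, and Gad1, which makes GABA, 265-fold. Gabra6, Scg2, Zcchc18, Calb1 and Pcp4 were 216-fold, 204-fold, 193-fold, 186-fold and 169-fold higher. All 18 measured genes of the neuron and synapse list were enriched in brain, including the neurofilament genes Nefm (159-fold) and Nefl (157-fold), although other probe sets of 1 of the 18 differed in the tissue with the highest level. All 10 genes of glutamate and GABA signalling were enriched, among them Gabrb2 (120-fold) and Gria2 (96.3-fold), as were 10 of 11 oligodendrocyte genes, with Olig1 63.7-fold higher. Of the astrocyte list 6 of 9 were enriched, led by S100b (120-fold), Aldoc (104-fold) and Gfap (48.4-fold), while Fgfr3 was 2.88-fold higher in lung than in the next tissue. Microglial genes did not follow the brain: P2ry12 was 2.70-fold higher in brain than in the next tissue, but Csf1r and Tmem119 were 2.24-fold and 2.65-fold higher in lung (Csf1r by 0.91, log2, under the 2-fold limit, after median centring). Aif1 had levels of 8.11 in lung, 7.77 in liver and 6.49 in brain, and Cx3cr1 and Itgam differed from the next tissue by 0.02 and 0.12 (log2), with limma adjusted p of 0.892 and 0.418. The microglial list did not rank high in brain by camera (adjusted p = 0.814, and 0.826 with an estimated correlation), unlike each other list of a home tissue. Counts adjusted over each list alone were equal to these. As deposited, brain had the most enriched probe sets, 3571 (11.5%). This rank may depend on scaling, since liver had 3463 after median centring and 3479 with the 5th percentile subtracted.

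Lung was marked by secretory and surfactant genes. Scgb1a1, the secretoglobin of airway club cells, reached 14.04 ± 0.02 (log2, SD, n = 3) in lung and 3.85 ± 0.27 in liver, a 1168-fold difference. The surfactant genes Sftpc, Sftpa1 and Sftpb were 681-fold, 624-fold and 490-fold higher than in the next tissue, the chemokine gene Cxcl3 739-fold and Lamp3 454-fold. In the mixtures Scgb1a1 and Sftpc lay 1.98 (log2) above linear mixing on average, which limits what their folds in pure tissue can show. Sec14l3 was 307-fold, Ly6i 289-fold, the defensin gene Defb4 289-fold and Mfap4 216-fold higher. All 9 measured alveolar type 2 genes and all 6 type 1 genes were enriched in lung, the latter with Ager (73.7-fold), Aqp5 (27.4-fold) and Cav1 (24.0-fold). Airway club and ciliated cell genes were enriched in 6 of 8 cases, including Bpifa1 (26.2-fold) and Scgb3a1 (23.4-fold). All 10 endothelial genes were enriched, with Ramp2, Vwf and Calcrl 12.2-fold, 11.6-fold and 11.5-fold higher. Matrix and smooth muscle genes followed in 10 of 12 cases, led by Col1a1 (23.4-fold), Col1a2 (19.3-fold) and Tagln (15.5-fold). Macrophage and white blood cell genes did so in 11 of 13, led by Lyz2 (23.0-fold), S100a9 (15.1-fold) and S100a8 (10.3-fold). Adjusted over the list alone the counts were equal. Lung had 2777 enriched probe sets (8.95%).

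Between pairs of tissues, 10393 probe sets differed at least 2-fold between liver and brain by limma with Benjamini-Hochberg adjustment, 4539 of them higher in liver. Liver and lung differed in 8698, 3367 of them higher in liver, and brain and lung in 9617, 4666 of them higher in brain. The share higher in liver depended on the scaling. It was 43.7% against brain and 38.7% against lung as deposited, and 57.3% and 56.2% after centring arrays on their medians. It was 16.7% and 10.1% when each array was shifted by a curve through its hybridisation controls, a setting chosen after seeing the data. Those settings moved the median difference of liver minus brain from 0.18 (log2) to 0.42 and -0.66. The corresponding medians of liver minus lung were 0.12, 0.37 and -0.80, and those of brain minus lung -0.03, -0.02 and -0.11. The bioB controls lay at 8.48 (log2) in liver, where upper quartiles of the arrays were 7.27 to 7.30. In brain they lay at 7.62, against upper quartiles of 7.49 to 7.52. Most values there were thus below the dimmest control and took its shift, so the shares after that curve rest mainly on bioB.

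Several lists chosen to cover other cell types also differed between tissues. Heart muscle genes were enriched in lung in 7 of 9 measured cases, with Myh6 at 9.32 ± 0.05 (log2, SD, n = 3) in lung against 4.02 ± 0.40 in liver, Myl7 29.9-fold and Myl4 7.66-fold higher than in the next tissue, while Ryr2 was 12.4-fold higher in brain. The list ranked high in lung by camera (adjusted p = 0.00329, and 0.00636 with an estimated correlation). It ranked low in liver (adjusted p = 0.0109, and 0.0165 with an estimated correlation). Skeletal muscle genes were enriched nowhere (0 of 7), with Acta1 at 9.29 in lung and 8.33 in liver, and ranked low in brain (adjusted p = 0.0109, and 0.0165 estimated). After the curve through the hybridisation controls, however, Acta1, Tnnt3, Tnni2 and Ckm passed the 2-fold limit in lung, at 1.90, 1.67, 1.49 and 1.41 (log2). Cell division genes were enriched in lung in 5 of 8 cases, led by Cdk1 (6.16-fold), Mki67 (4.30-fold) and Ccna2 (4.28-fold), with a camera adjusted p of 0.00388 and 0.0133 with an estimated correlation. Of the red blood cell list, Hbb and Ahsp were 2.53-fold and 2.86-fold higher in lung than in the next tissue. Its camera adjusted p of 0.0475 in lung became an adjusted p of 0.136 with an estimated correlation, and that of 0.0283 in brain, where it ranked low, became 0.105. Immediate early and heat shock genes went both ways: Egr1 and Fos were 5.16-fold and 2.65-fold higher in brain, and Hspb1 and Ier2 11.9-fold and 2.25-fold higher in lung, with 2 of 9 measured genes enriched in brain and 4 in lung. Cidec was 18.5-fold higher in liver and Fabp4 6.47-fold in lung, the 2 enriched genes of the fat list, which ranked low in brain (adjusted p = 0.0136, and 0.0237 estimated). Adipoq of that list passed the 2-fold limit in lung with the 5th percentile subtracted (1.19, log2) and after the curve through the hybridisation controls (1.48). So did Alas2 of the red blood cell list (1.70) and the microglial Aif1 (1.29) after that curve. Of the choroid plexus list Otx2 (5.04-fold) and Folr1 (2.31-fold) were enriched in brain and Aqp1 (4.26-fold) in lung. After median centring Ier2 and Folr1 stood at 0.91 and 0.97 (log2), under the 2-fold limit. No pituitary gene (0 of 7), reference gene (0 of 8), ribosomal protein gene (0 of 9) or respiratory chain gene (0 of 14) was enriched in any tissue as deposited. Of the pituitary genes, Pomc passed the limit in liver after centring (1.197, log2), quantile normalization (1.01) and subtraction of the 5th percentile (1.46). Cga and Tshb passed it in brain after that subtraction (1.04 and 1.57) and after the curve through the hybridisation controls (1.67 and 1.30). Ribosomal protein genes nevertheless ranked high in lung as a list (median 0.75, camera adjusted p = 3.84e-05, and 0.00304 with an estimated correlation), as did respiratory chain genes in brain (median 0.48, adjusted p = 2.74e-04, and 0.0269 estimated). Respiratory chain genes ranked low in lung (median -0.79, adjusted p = 2.39e-06, and 0.00567 estimated). In liver, respiratory chain genes ranked high with an adjusted p of 0.0283, which became an adjusted p of 0.149 with an estimated correlation. Ribosomal protein genes ranked low in brain with an adjusted p of 0.0419, which became 0.105, and low in liver with an adjusted p of 0.0109, which became 0.0497 and, after median centring, 0.142. The call of ribosomal genes in lung and of respiratory chain genes in brain ended after the curve through the hybridisation controls, with adjusted p of 0.651 and 0.997. Mean levels of Tnnt3, Tnni2, Ckm, Adipoq, Cga and Tshb lay below the bioB controls, so their values after that curve rest on the bioB shift.

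Levels in the mixtures were set against the share-weighted sum of the pure tissues on the linear scale. The surfactant gene Sftpc and the club cell gene Scgb1a1 lay above that sum by a mean of 1.98 (log2) each over the 11 mixtures, and Lyz2 by 1.74, and all 11 mixtures had the same sign for each. Rup2 and Cyp2c7, both bright in liver, lay above it by 1.02 each. On the other side stood genes with their highest level in liver but a modest brightness there: Mbnl3 (-1.50 ± 0.09, SE), the nuclear receptor gene Nr1i3 (-1.38 ± 0.11), Wfdc3 (-1.36 ± 0.08), Mmp19 (-1.36 ± 0.09) and Tnfaip8l1 (-1.36 ± 0.07). By limma, 1604 probe sets (5.17%) departed by at least 1.5-fold, 101 above and 1503 below the sum. A share-weighted mean of log2 values never exceeds the log2 of the share-weighted sum, so departures from it can only be higher. Against it 3275 departed, 3103 above and 172 below, and Mbnl3 and Wfdc3, at -0.55 and -0.52, were no longer called. The direction of that change was fixed by arithmetic and does not bear on the balance against the linear sum. Among liver-enriched probe sets at levels of 6 to 8 in liver, 409 of 539 lay below, and of those over 12, 40 of 117 lay above and 0 below. Of the brain-enriched probe sets 16 lay above at levels of 8 to 10, 27 at 10 to 12 and 11 over 12, and 0 lay below at any level. Of the lung-enriched probe sets 9 lay below at levels under 6, 57 at 6 to 8 and 11 at 8 to 10, while 1 lay above at 10 to 12 and 6 over 12. Predicted and observed levels correlated across probe sets, which are not independent replicates, at r = 0.990 or higher in each mixture. The median departure over all probe sets was -0.22, and between 90.8% and 98.1% of probe sets lay within 1.5-fold of the sum. Even probe sets with a range under 0.5 (log2) between tissues, for which any shares predict little change, had a median of -0.21. Such an offset favours calls below the sum, so the balance of 101 above and 1503 below partly reflects it. How large that part is was not tested. The count of departures was 209 after the curve through the hybridisation controls and 4950 after median centring.

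Tissue shares were then estimated in each mixture array from the 100 most enriched probe sets of each tissue. The mixture with 1% lung (65/34/1) was estimated at 0.28 ± 0.03% lung (SD, n = 3), and that with 70% brain (25/70/5) at 72.2 ± 0.24% brain. Estimates of liver were too low in 10 of 11 mixtures, with an error of -8.68 points in 70/25/5, and those of brain too high in 11 of 11. The mean error was -4.49 points for liver (exact sign-flip test over 11 mixtures, two-sided, p = 0.00195, adjusted over 3 tissues 0.00293), 5.72 points for brain (p = 9.77e-04 by the same exact test, adjusted 0.00293) and -1.22 points for lung (p = 0.0771, exact test, adjusted 0.0771). All 11 errors rest on the same pure tissue means, so they are not independent, and these p-values do not cover an error of those means. The mean absolute error was 4.54, 5.72 and 1.80 points, against a median SD between replicate arrays of 0.24, 0.22 and 0.11 points. The direction depended on the probe sets and their weighting together. With all probe sets in place of the top 100, and without the division by the highest pure mean, the mean error was 6.68 points for liver and -1.67 for brain. Which of these 2 changes turned it was not tested. Estimated and labelled shares correlated over the 11 mixtures with r = 0.999 for liver, 0.993 for brain and 0.995 for lung (permutation p = 1e-05, the smallest the 100000 permutations can give, adjusted 1e-05). Spearman's rho was 0.993, 0.986 and 0.986 (permutation p = 1e-05, 1e-05 and 2.00e-05, adjusted 1.50e-05, 1.50e-05 and 2.00e-05). Without the 2 mixtures farthest from the median share, r was 0.995, 0.988 and 0.998.

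**Figure D1:**
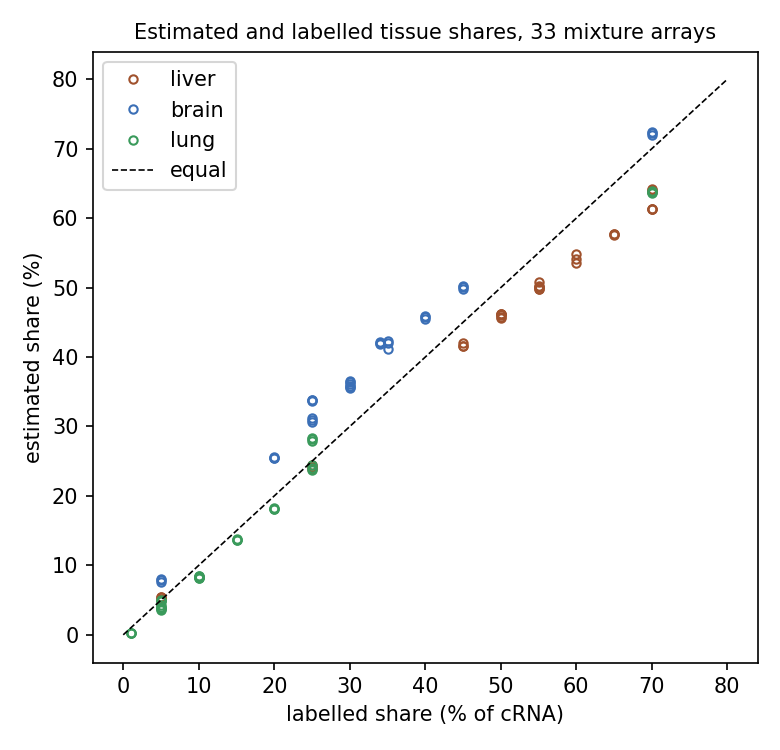
Estimated share (vertical, percent) against labelled share of cRNA (horizontal, percent) of liver, brain and lung on 33 mixture arrays, each circle 1 array and tissue, with the dashed line where both are equal. Brain lies above the line in all 11 mixtures, liver below it in 10 of 11.

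The error depended on the brightness of the genes used. From enriched probe sets, at least 4-fold higher than in both other tissues and at levels of 6 to 8 in their home tissue, the mean error was -22.0 points for liver and 19.8 for brain. It shrank with each brighter band and reached -0.42 points for liver and 1.41 for brain from probe sets over 12, where errors of both signs partly offset each other and the mean absolute error was 3.17 and 3.21 points, while lung stayed between -0.99 and 2.18. These bands were chosen after seeing the data.

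**Figure D2:**
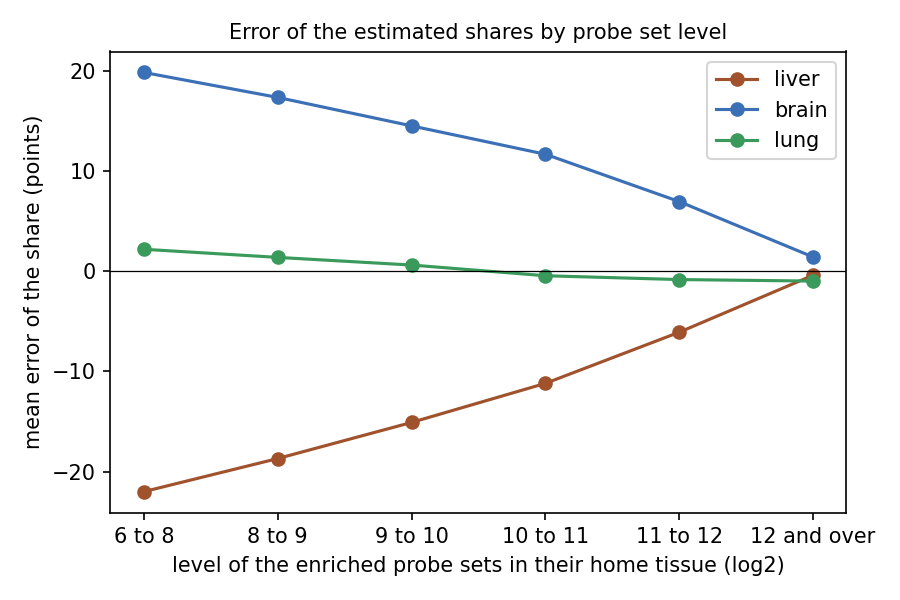
Mean error of the estimated share (vertical, percentage points, over 11 mixtures) by the level of the enriched probe sets in their home tissue (horizontal, log2) for liver, brain and lung. The error of liver runs from -22.0 to -0.42 points and that of brain from 19.8 to 1.41 points.

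The lowest shares were tested against the level predicted without the tissue. At 1% lung, the club cell gene Scgb1a1 was at 10.52 ± 0.01 (log2, SD, n = 3), 105-fold over the 3.81 predicted without lung, Sftpc was 64.0-fold over it and Sftpa1 16.2-fold. Cxcl3, Lamp3, Sftpb and Defb4 followed at 13.6-fold, 10.2-fold, 8.82-fold and 6.24-fold. In this mixture Scgb1a1 and Sftpc lay 3.01 and 2.87 (log2) above linear mixing, so their folds exceed what 1% lung predicts. Of the 100 top lung probe sets 57 were higher than predicted without lung and 2 lower, and 29 were higher after the curve through the hybridisation controls. The median rise of these 100 was 0.31 (log2), against 0.56 expected at 1% lung. Type 2 cell genes were higher in 7 of 9 cases and lower in 1, and type 1 genes higher in 4 of 6 and lower in 1, but endothelial genes in 2 of 10 with 7 lower, and white blood cell genes in 1 of 13 with 11 lower. Over all tested probe sets the median was -0.19 in this test, with 3335 called higher and 15652 lower, so the baseline itself was shifted. At 5%, all 100 top probe sets were higher for lung in 60/35/5, 25/70/5 and 70/25/5, for brain in 70/5/25 and for liver in 5/25/70. Over all enriched probe sets the counts were mixed. Of the 2777 of lung, 688 were higher and 691 lower in 60/35/5, 638 and 290 in 25/70/5, and 822 and 592 in 70/25/5. Of the 3571 of brain 2038 were higher and 124 lower in 70/5/25, and of the 2259 of liver 590 and 412 in 5/25/70. The median over all tested probe sets lay between -0.21 and -0.15 in these mixtures. At 5% liver, all 21 plasma protein genes were higher, 11 of 12 of bile acids, 11 of 12 of the urea cycle and amino acids and 3 of 5 of glucose production, but 7 of 16 of drug and steroid metabolism. At 5% brain, 17 of 18 neuron and synapse genes were higher, 8 of 10 of glutamate and GABA signalling, 9 of 11 of oligodendrocytes with 1 lower, 6 of 9 of astrocytes with 1 lower, and 1 of 6 of microglia with 1 lower. At 5% lung, in the order 60/35/5, 25/70/5 and 70/25/5, the higher genes numbered 8, 8 and 9 of 9 for type 2 cells, 5, 5 and 5 of 6 for type 1 cells, and 7, 9 and 9 of 12 for matrix and smooth muscle, with 0 lower. For airway cells 5, 4 and 5 of 8 were higher and 1, 1 and 2 lower, for endothelium 5, 8 and 7 of 10 higher and 2, 1 and 1 lower, and for white blood cells 6, 7 and 5 of 13 higher and 2, 4 and 3 lower.

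Mixtures that differ by a small exchange of tissue were compared in pairs. Where 20 points of brain were exchanged for lung (70/5/25 against 70/25/5), the lung genes Tbx5, Ccl11 and Prr15l were higher by 2.65, 2.52 and 2.49 (log2), and the brain-high genes Tmem229a, Ildr2 and Plcxd3 lower, at -2.55, -2.51 and -2.42. All 18 neuron and synapse genes were lower and all 9 type 2 cell genes higher, among 14522 probe sets called by limma. Linear mixing of the pure means predicted 1.74, 1.75 and 1.79 for Tbx5, Ccl11 and Prr15l. For Tmem229a, Ildr2 and Plcxd3 it predicted -1.58, -1.85 and -1.89, and for no probe set a change over 2.30 in size. These genes, chosen for the largest calls, thus changed more than the exchange predicts. Medians of the 100 top probe sets lay nearer, at 2.15 for lung (1.93 predicted) and -2.04 for brain (-2.15 predicted). With 10 points exchanged (55/20/25 against 55/30/15), 6087 were called, with Tbx5, Pof1b and Ighvl1 at 1.197, 1.08 and 1.05, Ildr2, Cdh7 and Sertm1 at -0.73, -0.70 and -0.68, and 17 of 18 neuron and synapse genes lower. The predictions were 0.62, 0.56 and 0.58 for Tbx5, Pof1b and Ighvl1, and -0.53, -0.47 and -0.43 for Ildr2, Cdh7 and Sertm1. With 4 points more lung, 1 more brain and 5 fewer liver (60/35/5 against 65/34/1), 775 were called, 686 of them higher, and 384 were called with only the 6 arrays of the pair. All 9 type 2 genes were higher, and Ly6i, Sec14l3 and Cxcl3 rose by 2.46, 2.28 and 2.23, whereas Sult1c2, Tesk2 and Chrna7 lay at -0.48, -0.40 and -0.39. Linear mixing predicted 2.01, 2.02 and 2.19 for Ly6i, Sec14l3 and Cxcl3, but only -0.099, -0.021 and -0.031 for Sult1c2, Tesk2 and Chrna7. With 5 points of lung exchanged for liver (55/30/15 against 50/30/20), 513 were called, 476 of them lower, among them Pof1b, Esm1 and Tbx5 at -0.64, -0.63 and -0.60 and 7 of 10 endothelial genes, while Kel, Ptprh and LOC102548988 lay at 0.46, 0.42 and 0.42. Here -0.31, -0.25 and -0.34 were predicted for Pof1b, Esm1 and Tbx5. For Kel, Ptprh and LOC102548988 only 0.015, 0.061 and 0.013 were predicted, so the exchange does not account for the size of their changes. Kel, Ptprh and Pof1b, and of the pair before it Sult1c2, Tesk2 and Chrna7, were no longer called when only the 6 arrays of each pair were fitted (adjusted p from 0.0546 to 0.167). LOC102548988 lost the call in 5 of 6 fits with an array left out (adjusted p from 0.104 to 0.18) and after quantile normalization (0.102). Kel also lost it in 5 of 6 such fits (0.0582 to 0.278) and after quantile normalization (0.111). Ptprh lost it without replicate 1 or 3 of either mixture (0.0512 to 0.149). Esm1 lost it without replicate 1 of 50/30/20 (0.0558), without replicate 3 of 55/30/15 (0.078) and after quantile normalization (0.0506), and Tbx5 lost it without replicate 3 of 55/30/15 (0.052). The count of 513 became 192 to 260 when any 1 of its 6 arrays was left out. With 5 points of liver exchanged for brain (45/45/10 against 50/40/10), limma called 0 probe sets. The smallest adjusted p was 0.0923, and 3915 passed an unadjusted p under 0.05. With an intensity trend and a robust prior 127 were called. The median of the 100 top liver probe sets was -0.15 there, and -0.15 was predicted. After the curve through the hybridisation controls the pairs with 20, 10, 4 and 5 points of lung exchanged had 5291, 14, 51 and 0 calls. That curve strongly shifts replicate 2 of 60/35/5, whose controls were high, and so adds spread to the fit shared by all pairs. How many calls were lost through this 1 array was not tested.

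Differences between tissues were also estimated from the mixtures alone, without any pure array, by regressing linear levels on the labelled shares. All 12 bile acid genes, all 18 neuron and synapse genes and all 9 type 2 cell genes were again higher in their home tissue than in both others. So were all measured genes of the other lists with a home tissue, except that the count was 13 of 16 for drug and steroid metabolism, 7 of 9 for astrocytes, 1 of 6 for microglia, 7 of 8 for airway cells and 11 of 12 for matrix and smooth muscle. For Mbp the brain level from mixtures was 1.26 times the measured pure level, for Snap25 1.27 times, for Sftpc in lung 1.41 times and for Slc2a2 in liver 0.957 times. By limma with a variance trend and no fold limit, 19134 probe sets differed between liver and brain, 18892 between liver and lung and 18926 between brain and lung. Without a fold limit the pure tissues differed in 26284, 25676 and 22256 in the same order. Of the probe sets called between pure tissues at 2-fold or more, 97.7%, 92.8% and 98.6% were called in the same direction. The fitted level was at or below 0 for 1763 probe sets in brain, 526 in lung and 0 in liver. Leaving out the only mixture with 70% lung lowered the liver against lung count to 10642.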

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

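Of the tests in this part, those of an excess of brain cRNA, of the signal ceiling, of the lung share and of other splits were chosen only after their results had been seen at least in part, and the curve through the hybridisation controls was added after seeing the data, with its bound for the share error written before that error was computed.

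The error of the estimated share differed between liver and brain: brain minus liver was 10.2 points on average and positive in 11 of 11 mixtures (exact sign-flip test, two-sided, p = 9.77e-04). Shares that sum to 100% tie both errors together. All mixtures also share the same pure means, an error of which this test does not cover. With all probe sets and no division by their highest pure mean, the direction turned (6.68 points for liver, -1.67 for brain). A constant excess of brain cRNA would make the brain error equal at every brightness. That error was 14.2 points larger from probe sets at 8 to 10 than from those over 12 (SD 7.73 over mixtures, larger in 11 of 11, exact sign-flip test, two-sided, p = 9.77e-04, with the same limit). This argues against such an excess as the only cause, though short of the 2 SD set to exclude it. Such an excess would also multiply the ratio of brain to liver by 1 factor in every mixture. From the top probe sets that factor ran from 1.07 to 1.71, with an SD (log2) of 0.19 between mixtures and 0.03 between replicate arrays. This too argues against it, unless the mixing itself varied. A smaller excess beside another cause stays open. If controls were added in equal amounts, which was not tested, uneven scaling of pure liver may account for part: shifting each array by them left 41.3% of the liver error from probe sets at 8 to 10 (-16.4 to -6.79 points), while the brain error went from 15.6 to 9.21. That shift did not lower the error of the usual estimate from the top probe sets. Its mean went from -4.49 to -4.68 points for liver and from 5.72 to 6.95 for brain. The top probe sets were chosen anew from the shifted values, so this comparison mixes the shift with that choice. It cannot decide whether uneven scaling accounts for the error of that estimate. No biological explanation was tested because the mixing was technical.

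The control probe sets outside the main measurement showed the bioB controls 0.86 (log2) higher in liver than in brain, at 8.48 ± 0.05 (SD, n = 3) against 7.62 ± 0.09, while the cre controls lay at 13.02 ± 0.05 in liver against 13.43 ± 0.04. In 60/35/5, the bioB controls of replicate 2 stood 1.48 above the middle array, at 9.35 against 7.88 and 7.65, and its bioC controls were at 10.61 against 9.30 and 9.06. Leaving out any 1 of the 6 arrays of 60/35/5 and 65/34/1, that array included, limma called 630 to 781 probe sets, against 775 with all.

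Sftpc, Scgb1a1 and Lyz2 lay far above linear mixing, by up to 3.01 (log2) for Scgb1a1. More lung cRNA than labelled is argued against, since 98 other top lung probe sets had a median departure of 0.0589 in the 9 mixtures with 5% to 25% lung. A ceiling of the signal in pure lung, where these genes lie at 13.87 to 14.04, is consistent with a departure that was smaller at 70% lung than at the median of those mixtures by at least 1.70. For Sftpc it was 0.44 at 70% lung and 2.23 at that median. Any other cause that vanishes in pure lung would shrink in the same way, so the test does not single out a ceiling, and no biological explanation was tested.

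Whether counts could arise from other groupings of the arrays was checked by regrouping. For 6 arrays only 10 splits exist, too few for a share under 0.05. In each comparison of 6 arrays with any calls, 1 split, the real one, reached the real count. The real counts were 10393 for liver and brain (highest other split 1), 8698 for liver and lung (3), 9617 for brain and lung (0), 513, 775, 6087 and 14522 for the pairs with calls (0 in each), while all 10 splits of 45/45/10 and 50/40/10 gave 0. Of 100 splits of the 9 pure arrays, 8 gave as many enriched probe sets as the real 2259 of liver, 3 as many as the 3571 of brain and 8 as many as the 2777 of lung, with a highest other of 4288. That share is under 0.05 for brain and over it for liver and lung, but it cannot decide on chance for any tissue. It counts splits that keep the 3 arrays of 1 tissue together as the enriched group, and so hold a real difference between tissues. All 7 other splits that reached the liver or lung count, and both that reached the brain count, were of that kind. The highest count without a whole tissue was 967, under all 3 real counts. Of 100 assignments of shares to mixtures, 1, the real one, gave as many probe sets as the mixtures-only counts of 19134, 18892 and 18926, with a highest other of 6638, 7602 and 7693, so chance can be excluded there.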

How the results depend on the processing

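The shares by brightness and the curve through the hybridisation controls were chosen after seeing the data. No paired analysis was possible because the labels give no replicate numbers that link arrays across groups. The next tally covers named genes and the counts of enriched genes in lists with a home tissue. In it, 2918 comparisons with an alternative kept direction and side of the threshold or, for list counts, stayed within the limits set. Of the others, all for single genes, 55 lost the call, 15 gained it and 12 reversed. Camera calls of single lists, some of which ended as given above, are not in it. Among counts and shares, 528 stayed within the limits set and 85 moved. Where no cause is named below, the cause was not tested.

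With 1 probe set per gene, and so fewer tested, liver against brain had 5584 calls, liver against lung 4879, brain against lung 5164, and 1366, 1669 and 1635 were enriched in liver, brain and lung. Liver-enriched probe sets numbered 3463 after centring, 3479 with the 5th percentile subtracted and 1145 after the control curve, under which liver against lung had 14072 calls. Departures numbered 4950 after centring, 2801 after quantile normalization, 948 with estimated shares and 209 after the control curve. With log2 mixing, which can only raise departures, they numbered 3275 (3103 above and 172 below, against 101 and 1503 as reported).

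The mean absolute error of the liver, brain and lung share was 6.01, 4.76 and 2.21 points with the top 25, 5.10, 5.30 and 1.10 with the top 50, and 5.65, 7.18 and 2.19 with the top 250. It was 6.68, 2.42 and 5.01 with all probe sets, not divided by their highest pure mean. With log2 values it was 11.4, 11.1 and 3.70, and after quantile normalization 2.87, 3.81 and 1.70. With the lowest pure mean subtracted it was 4.71 for liver and 1.68 for lung. From probe sets at 8 to 10 it was 16.4, 15.6 and 2.24, from those over 12 it was 3.17, 3.21 and 1.53, and after the control curve 4.83, 6.95 and 2.27. Leaving out each array gave 4.51 to 4.80 for liver, 5.62 to 5.98 for brain and 1.54 to 1.82 for lung.

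At 1% lung, 24 of the top 25, 90 of the top 250 and, after the control curve, 29 of the top 100 probe sets were higher. For 55/30/15 against 50/30/20, 235 were called with only the 6 arrays of the pair, 326 after centring, 276 after quantile normalization, 0 after the control curve and 192 to 260 with an array left out. For 60/35/5 against 65/34/1, 384 were called with only the 6 arrays and 51 after the control curve. For 45/45/10 against 50/40/10, 127 were called with an intensity trend and robust prior, 1 after centring, 34 after quantile normalization and 56 among brighter probe sets. The control curve left 14 calls for 55/20/25 against 55/30/15 and 5291 for 70/5/25 against 70/25/5. It adds the noise of few control probe sets to each array, gives values below bioB the bioB shift and assumes equal amounts of control. The high controls of replicate 2 of 60/35/5, at an ordinary median of all values, put that assumption in doubt for this array. From mixtures alone, liver against lung had 10642 calls without the 5/25/70 mixture and 19922 without 70/5/25.

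Cx3cr1, taken as brain over the next tissue (log2), was -0.23 after centring, -0.23 after quantile normalization, -0.07 and -0.0038 without liver replicates 2 and 3, and from -0.11 (without brain replicate 1) to 0.13 over all arrays left out. Itgam in liver was -0.74 after the control curve and from -0.056 (without liver replicate 2) to 0.25 with an array left out. After the control curve Slc4a1, Cfd, Lhb, Kcnj13 and Cox5a, highest in liver as deposited, were -0.27, -0.60, -0.55, -0.32 and -0.14. Arrays have no read depth, and probe sets near background limit the smallest share that can be seen.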

Other observations

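The test of the atrial genes was chosen only after their levels had been seen. Heart muscle genes in lung could come from a piece of ventricle carried over, or from the atrial-type muscle that lines lung veins. The first is argued against: Myl2, Myl3, Myh7 and Irx4 lay at 3.19, 5.46, 2.98 and 3.04 (log2) in lung, with a median of -0.86 over the higher of brain and liver, while the heart list's Myh6 lay at 9.32. The atrial genes had a median of 2.26 above that level, with Myl7 at 4.90, Myl4 at 2.94 and Sln at 1.58, but Nppa, abundant in atrium, at -0.47 and so not above it. The second explanation therefore stays open.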
